A study of Homo sapiens with 36 samples.

How the data were processed

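Gene expression was measured in the breast cancer cell lines MDA231, SUM159PT and BT549 on 36 single-colour Affymetrix arrays labelled by the maker's whole-transcript sense protocol. The labels give each line 4 groups of 3 arrays with the replicate letters A, B and C, which makes 12 groups. Cells were reverse transfected with 10 nM siRNA, control or against DUSP4, and harvested after 96 h, and DMSO or 1 uM selumetinib was present for the last 4 h or 24 h. The groups were taken from the sample titles. For 24 arrays the titles and the cell line field disagree with the source name and description over SUM159PT and BT549, and the titles were followed. The labels do not say whether the letters mark separate cultures, so p-values measure only the spread between these samples, which may be technical.

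The deposited values are on a log2 scale and were made with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA in general corrects the background, applies quantile normalization and summarises probes by median polish. The options used, the level of summary and the genome build of the array design are not given in the sources used here. On the deposited scale the array medians ran from 5.12 to 5.40 and the upper quartiles from 7.48 to 8.03, so the arrays were not at exactly equal distributions. The lowest upper quartiles belonged to the MDA231 4 h array B (7.48) and the BT549 24 h array A (7.50). The next lowest was that of the MDA231 4 h array C (7.66). No 2 arrays held identical values, and the mean correlation of an array with the others of its group was 0.9863 to 0.9977. The number of arrays limits the precision.

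The value table holds 33297 probes. The probe annotation lists 21236 of them, 19181 with 1 gene symbol and 2055 with several, and the other 12061 are unnamed here. Of the single-gene probes, 19143 were matched to the reference by gene ID, and 0 symbols needed an update. Only probes with 1 symbol were used, and for the 895 genes with more than 1 such probe the probe of highest mean over all arrays was kept, which gave 17958 genes. No filter on dim genes was applied. No coordinates are given.

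One linear model with a mean for each of the 12 groups was fitted to all 36 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 24 residual and 7.8 prior degrees of freedom). All adjusted p-values for genes come from limma with the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were siDUSP4, selumetinib 4 h and selumetinib 24 h against siCONTROL in each line and as the mean of the 3 lines, 24 h against 4 h of selumetinib, and an F test of whether each effect differed between lines. Values are log2 changes with limma's standard error (SE). Percentages of a control level are 2 to the power of the log2 change.

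Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 21 lists within a comparison, and again with a correlation estimated for each list. The lists were MAPK output, DUSP family, AP-1 and immediate early, inflammatory cytokines, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and D cyclins, BCL2 family, interferon response, antigen presentation, receptor tyrosine kinases, mesenchymal, epithelial, breast stem-like markers, proteases and invasion, YAP targets, cholesterol synthesis, MYC and ribosome biogenesis, integrated stress response, lysosome, and blood and endothelial markers of other cell types. They were fixed from general knowledge, and some genes are on more than 1 list. Members were counted as called over all genes and as adjusted over the list alone.

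The genes named were chosen by a rule. It took DUSP4, the 8 largest mean rises and 8 largest mean falls of each treatment among called genes with the same sign in all 3 lines, up to 4 called members of each list with the smallest adjusted p, or the member of smallest p where none was called, the 3 largest rises and falls in each line, the 5 largest rises and falls of 24 h against 4 h, and the 5 genes per treatment with the smallest p for a line difference. Symbols of unnamed loci and small RNAs were passed over. The rule picked 217 genes, of which 98 are named and 119 were left out of the text. Another 6 genes are named outside the rule, as said where they appear.

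The relation of siDUSP4 to selumetinib changes was measured by correlation and covariance across genes. Because both share siCONTROL arrays, 100 pairs of unchanged groups against the same controls were simulated. With random seed 1, other divisions of the arrays were refitted, all 10 for 3 arrays against 3 and 100 drawn ones for results over the 3 lines. An exact test of 3 against 3 arrays cannot go below 0.1, and none was used.

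The alternatives were arrays of the line or of the 2 groups alone, the replicate letter as a block, repeated quantile normalization, aligned array medians, a filter at the median probe level of 5.328, all probes of the table, a 1.5-fold threshold, eBayes with trend and robust options, array weights, leaving out each array in turn, an estimated correlation, genes found on 1 list only, and selumetinib changes of the other lines. After the data were seen, 6 were added. These were leaving out the 2 arrays of narrowest signal range, the upper quartile as a covariate, repeated quantile normalization for the lists and for the correlations, aligned medians for the lists, and leaving out each array in turn for the overlaps of siDUSP4 with selumetinib.

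The code was tested on simulated arrays of the 17958 genes with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. For siDUSP4 in MDA231, 61.2%, 98.5% and 100% were recovered, and 9.42% of calls were false. For the mean of the lines 97%, 100% and 100% were recovered with 6.16% false, and for line differences 32.8%, 86.6% and 100% with 3.95% false. A shift of 0.3 given to the G2/M and mitosis list was recovered, and it was the only list called. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.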

Results

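Gene expression was measured on 36 Affymetrix arrays from 3 human breast cancer cell lines, MDA231, SUM159PT and BT549, all derived from tumours without hormone receptor or HER2 dependence. MDA231 (MDA-MB-231) carries a BRAF mutation, SUM159PT carries HRAS and PIK3CA mutations, and BT549 has lost RB1. Each line had 4 groups of 3 arrays. Control cells received 10 nM of a non-targeting siRNA and the vehicle DMSO (siCONTROL), and a second group received 10 nM of siRNA against DUSP4 (siDUSP4). The other groups were control-siRNA cells exposed to 1 uM selumetinib, an inhibitor of the kinases MEK1 and MEK2 upstream of ERK, for the last 4 h or 24 h before all cells were harvested 96 h after transfection. The design asks how gene expression changes when MEK is inhibited and when DUSP4 is lost. DUSP4 encodes a nuclear phosphatase that inactivates ERK and related MAP kinases, so both arms act on the same signalling pathway. All 17958 genes represented by a probe with a single gene symbol were tested. The number of arrays limits the precision, and because the labels do not say that the 3 replicates were separate cultures, the p-values measure only the spread between these samples, which may be technical.

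The sample labels conflicted for 24 of the 36 arrays. For these arrays the sample title and the cell line field named one of SUM159PT and BT549, and the source name and description named the other. The arrays were grouped by title, and every statement about SUM159PT or BT549 rests on that choice, whereas statements about MDA231 and about the mean of the 3 lines do not. RB1, the retinoblastoma gene whose product restrains E2F, had a log2 signal of 6.83 ± 0.16 (SD, n = 3) in siCONTROL arrays titled BT549, compared with 10.31 ± 0.09 in MDA231 and 9.40 ± 0.01 in arrays titled SUM159PT. CDKN2A, a CDK inhibitor locus that is highly expressed in many RB1-deficient cells, stood at 9.82 ± 0.11 in the arrays titled BT549 and at 4.23 ± 0.17 and 4.12 ± 0.09 in MDA231 and SUM159PT. Its neighbour CDKN2B stood at 8.30 ± 0.22 against 4.27 ± 0.09 and 4.31 ± 0.16. These 3 genes were chosen after their values were seen.

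DUSP4 itself fell in all 3 lines after siDUSP4. In MDA231, which had the highest control signal, DUSP4 went from 10.06 ± 0.08 to 7.64 ± 0.18 (log2, SD, n = 3), which left 18.7% of the control level. The change was -1.84 in SUM159PT, from 7.14 ± 0.12 to 5.30 ± 0.02, and -2.24 in BT549, from 7.13 ± 0.09 to 4.89 ± 0.40, leaving 27.9% and 21.1%. Averaged over the lines, DUSP4 fell by 2.17 ± 0.10 (SE; limma adjusted p = 1.2e-16), ranking 1 among all falls by size. The siDUSP4 means of SUM159PT and BT549 lay below the median probe level of 5.328, and no separate measure of background was available. Dim signal limits these percentages, and fall sizes were not compared between lines. DUSP4 transcript also fell with selumetinib. After 4 h, 19.6% of the control signal remained in MDA231 and 39.3% in SUM159PT, and after 24 h, 41.8% and 55.4%. In BT549 the 4 h value of 63.1% did not pass the test (change -0.66, adjusted p = 0.062), and the 24 h value of 60.6% did (change -0.72).

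**Figure D1:**
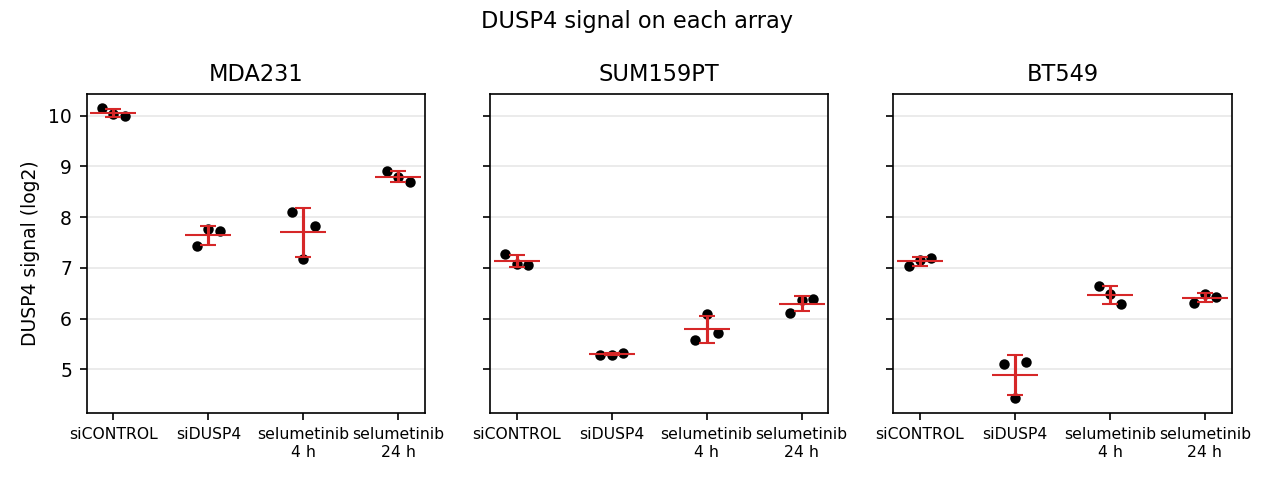
DUSP4 signal on each of the 36 arrays (vertical axis, log2), by treatment group (horizontal axis) and cell line (panel). Points are single arrays, and the red lines give the mean and SD of the 3 arrays of a group; in each line the siDUSP4 mean (7.64 in MDA231, 5.30 in SUM159PT and 4.89 in BT549) was the lowest of the 4 groups.

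In the mean of the 3 lines, mesenchymal genes were lower after siDUSP4. Antigen presentation, proteases and invasion, and G1/S and DNA replication genes also passed the test at the preset correlation, the first pair lower and the last higher, but not with an estimated correlation (adjusted p = 0.43, 0.52 and 0.43). Of 21 measured mesenchymal genes, 12 fell (13 when adjusted over the list alone) and none rose. Among them, the matrix glycoprotein gene SPARC changed by -0.76 ± 0.07 (SE, mean log2 change of the 3 lines), COL6A3, a collagen VI chain, by -0.73 ± 0.07, the cadherin gene CDH11 by -0.68 ± 0.05 and POSTN, encoding periostin, by -0.68 ± 0.09. The median of the list was -0.28 (camera adjusted p = 6.4e-12, and adjusted p = 0.0018 with an estimated correlation). It was the only one of the 21 lists whose call for the mean siDUSP4 effect held with an estimated correlation.

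Antigen presentation genes followed the same direction, with 10 of 16 lower and none higher (10 lower and 1 higher when adjusted over the list alone). CD74, the class II invariant chain, changed by -2.05, -1.84 and -0.66 in MDA231, SUM159PT and BT549, and HLA-DRA, a class II chain, by -2.57 and -1.85 in the first 2 lines, with -0.08 (not called) in BT549. CIITA, the class II transactivator, changed by -0.36 ± 0.06 on average. This list had a median of -0.19 and a camera adjusted p of 2.6e-07, which was lost as an adjusted p = 0.43 with an estimated correlation. Genes of proteases and invasion were mostly lower, with 12 of 21 lower and 2 higher (13 and 3 over the list alone; median -0.20, adjusted p = 0.0018, and adjusted p = 0.52 with an estimated correlation). MMP14, a membrane-bound matrix protease, changed by -0.71 ± 0.07 and its inhibitor TIMP2 by -0.78 ± 0.05. The collagenase gene MMP1 fell by 1.74 in SUM159PT and 1.98 in BT549, whereas MMP3, encoding stromelysin, rose by 3.51 in MDA231 and was also called higher in BT549.

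Of 28 G1/S and DNA replication genes, 13 were higher and none lower in the mean of the lines (17 higher over the list alone; median 0.20, adjusted p = 1.7e-10, and adjusted p = 0.43 with an estimated correlation). In MDA231, 8 were higher and 4 lower (9 and 5 over the list alone; adjusted p = 0.063), and in SUM159PT 1 was higher and none lower (1 and 2 over the list alone; median -0.07, adjusted p = 0.66), or 1 and 3 after aligning array medians. CCNE1, which encodes cyclin E1, rose by 2.16 in MDA231 and 0.80 in BT549, and CDC25A, a phosphatase that activates CDK2, rose in every line (1.16, 0.43 and 0.90 in MDA231, SUM159PT and BT549). The replication factor MCM10 and the ribonucleotide reductase subunit RRM2 changed by 0.61 ± 0.07 and 0.65 ± 0.09 on average. MYC and ribosome biogenesis genes showed 3 of 22 higher and none lower, both over all genes and over the list alone (median 0.08, adjusted p = 0.012, and adjusted p = 0.74 with an estimated correlation), among them ODC1, an enzyme of polyamine synthesis, at 0.24 ± 0.05. Both after repeating the quantile normalization and after aligning array medians, 9 of these 22 were higher and none lower. Integrated stress response genes had 8 of 18 lower and 1 higher (8 and 2 over the list alone; median -0.13, adjusted p = 0.0029, and adjusted p = 0.74 with an estimated correlation). ASNS, the asparagine synthetase gene, and DDIT4, an mTORC1 inhibitor gene, changed by -1.53 and -1.25 in MDA231.

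None of 29 measured MAPK output genes was higher after siDUSP4 in the mean of the lines, and 9 were lower (the same numbers over the list alone; median -0.09, adjusted p = 0.0026, and adjusted p = 0.89 with an estimated correlation). SPRY1, a feedback inhibitor of receptor signalling, changed by -0.76 ± 0.06, TRIB2 by -0.83 ± 0.09 and PHLDA1 by -0.39 ± 0.07. DUSP6, the cytoplasmic ERK phosphatase gene that follows ERK activity closely, was at -0.22, 0.04 and -0.06 in MDA231, SUM159PT and BT549, none of them called. In MDA231, 8 MAPK output genes were lower and none higher, over all genes and over the list alone (median -0.30, adjusted p = 4.3e-05, and adjusted p = 0.53 with an estimated correlation), or 12 and 1 after repeating the quantile normalization. In SUM159PT 2 were lower (4 over the list alone; adjusted p = 0.25). In BT549, 2 MAPK output genes were higher and 7 lower (3 and 9 over the list alone; median 0.05, with the test downward, adjusted p = 0.53), or 7 and 5 after aligning array medians (median 0.19, adjusted p = 0.29). AP-1 and immediate early genes in BT549 had 3 of 19 higher and 1 lower, over all genes and over the list alone (median 0.23, adjusted p = 0.02, and adjusted p = 0.59 with an estimated correlation), or 11 and 1 after aligning medians (median 0.37, adjusted p = 0.014). Among them EGR1, an immediate early transcription factor gene, rose by 1.31 (adjusted p = 1.1e-06).

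For the other 14 lists the mean siDUSP4 effect did not pass the camera test. Higher and lower members numbered 1 and 1 of 9 in the DUSP family (adjusted p = 0.85), 3 and 3 of 19 in AP-1 and immediate early genes (0.56), 5 and 4 of 19 in inflammatory cytokines (0.69; 6 and 5 over the list alone), 1 and 4 of 27 in G2/M and mitosis genes (0.48; 1 and 3 over the list alone), and 2 and 1 of 9 in CDK inhibitors and D cyclins (0.48). They numbered 2 and 2 of 15 in the BCL2 family (0.95), 6 and 5 of 25 in the interferon response (0.85; 6 and 6 over the list alone), 1 and 5 of 24 in receptor tyrosine kinases (0.21), 1 and 4 of 19 in epithelial genes (0.48), and 2 and 5 of 18 in breast stem-like markers (0.21). The last groups were YAP targets with 3 and 1 of 14 (0.52; 4 and 2 over the list alone), cholesterol synthesis with 1 and 3 of 16 (0.57), and lysosome genes with 3 and 3 of 17 (0.52; 6 and 7 over the list alone). Where no other count is given, the numbers over the list alone were the same. After aligning array medians the numbers were 7 and 3 in lysosome genes, 6 and 3 in AP-1 and immediate early genes, 3 and 3 in G2/M and mitosis genes, 3 and 3 in epithelial genes and 2 and 2 in cholesterol synthesis. After repeating the quantile normalization they were 7 and 7 in lysosome genes and 3 and 4 in epithelial genes. Blood and endothelial markers, which the lines are not expected to express, had 1 higher and 1 lower of 14 (adjusted p = 0.85), LYZ at 0.27 ± 0.07 and PECAM1 at -0.41 ± 0.08. In the BCL2 family list the median was -0.02 and the mean -0.01 while the test pointed upward, and in the blood and endothelial list they were 0.00 and -0.01 with the test upward. In the DUSP family they were 0.00 and -0.03 with the test downward. ITGA6, the integrin alpha 6 gene among the stem-like markers, fell in every line (-1.11, -0.46 and -1.32 in MDA231, SUM159PT and BT549).

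Counted over all genes, siDUSP4 changed 3166 genes in MDA231 (1412 higher, 1754 lower), 509 in SUM159PT (189 and 320), 2548 in BT549 (892 and 1656) and 3357 in the mean of the lines (1335 and 2022). Of the genes called in the mean, 2390 had the same sign of change in all 3 lines. In each line separately, 72 genes fell in all 3 lines and 12 rose in all 3, where independent lists of these sizes would share 2.88 and 0.738. Another 259 had opposite calls between lines, not compared with chance. FNBP1L, which encodes a membrane-curving adaptor protein, the proteasome subunit gene PSMB5 and the metalloreductase gene STEAP3 were among the largest mean falls (-1.37 ± 0.07, -1.45 ± 0.08 and -1.26 ± 0.06), and ATP6V0D2, a subunit of the vacuolar proton pump, had the largest mean rise (1.76 ± 0.12, led by 3.57 in MDA231). The balance of rises and falls depended on scaling. Lower genes made up 60.2% of those called in the mean, against 47.8% after repeating the quantile normalization (2429 higher, 2220 lower) and 38.2% after aligning array medians (2760 and 1708). In BT549 the shares were 65.0%, 49.8% (1869 and 1852) and 27.3% (2950 and 1106), and aligning medians moved the median change of all genes in BT549 from 0.01 to 0.15. In SUM159PT they were 62.9%, 52.0% (564 and 611) and 62.3%. Leaving out any 1 of the 6 arrays lowered the SUM159PT count to 290 (without siCONTROL A), 303 (siCONTROL B), 337 (siCONTROL C), 291 (siDUSP4 A), 334 (siDUSP4 B) or 339 (siDUSP4 C), and leaving out siCONTROL B lowered the BT549 count to 1548.

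The response to siDUSP4 differed between lines for 2790 genes (limma F test of the line differences). In BT549, G1/S and DNA replication genes rose broadly, with 22 of 28 higher and none lower (25 over the list alone; median 0.64, adjusted p = 1.1e-24, and adjusted p = 0.025 with an estimated correlation). E2F2, an activating E2F factor, rose by 1.46 in BT549 and RRM2 by 1.29. This list rose more in BT549 than in SUM159PT (median difference SUM159PT minus BT549 of -0.69, adjusted p = 1.2e-21, and adjusted p = 0.043 with an estimated correlation). Mesenchymal genes fell in BT549, with 15 of 21 lower and none higher, the same numbers over the list alone (median -0.68, adjusted p = 5.5e-19, and adjusted p = 8.6e-05 with an estimated correlation), COL6A3 and SPARC at -1.21 and -1.36. In MDA231 the list did not pass the test, with 5 lower and 1 higher (the same over the list alone; median -0.11, adjusted p = 0.2). In SUM159PT 4 were lower (7 over the list alone; median -0.22, adjusted p = 0.00044, and adjusted p = 0.34 with an estimated correlation). The difference of MDA231 from BT549 had a median of 0.62 and that of SUM159PT from BT549 a median of 0.52, and both held with an estimated correlation (adjusted p = 0.0066 and adjusted p = 0.0037). After aligning array medians the BT549 medians were 0.78 for replication genes and -0.54 for mesenchymal genes. G2/M and mitosis genes went opposite ways in MDA231 and BT549. In MDA231, 8 of 27 were lower and none higher (11 lower over the list alone; median -0.23, adjusted p = 4.3e-05, and adjusted p = 0.53 with an estimated correlation). In BT549, 10 were higher and 1 lower (13 and 1 over the list alone; median 0.23, adjusted p = 3.1e-05, and adjusted p = 0.44 with an estimated correlation), or 16 and 1 after repeating the quantile normalization and 19 and 0 after aligning medians. In SUM159PT 1 was lower, over all genes and over the list alone (median -0.13, adjusted p = 0.013, and adjusted p = 0.72 with an estimated correlation). The difference of MDA231 from BT549 had a median of -0.50, with 14 of 27 genes lower and none higher (18 over the list alone; adjusted p = 1.1e-10, and adjusted p = 0.22 with an estimated correlation).

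Interferon response genes moved in opposite directions. In BT549, 12 of 25 fell and 1 rose (13 and 2 over the list alone; median -0.35, adjusted p = 4.5e-07, and adjusted p = 0.36 with an estimated correlation), and IFIT1 and IFIT2, both antiviral genes induced by interferon, changed by -1.77 and -1.54. In SUM159PT, 5 rose and none fell (7 over the list alone; median 0.13, adjusted p = 5.4e-06, and adjusted p = 0.43 with an estimated correlation). The difference of SUM159PT from BT549 had a median of 0.54 (adjusted p = 4.8e-14, and adjusted p = 0.046 with an estimated correlation). In MDA231, IFIT1 and IFIT2 rose by 0.76 and 1.06. MDA231 also showed higher inflammatory cytokine transcripts, with 8 of 19 higher and 3 lower (9 and 3 over the list alone; median 0.26, adjusted p = 6e-04, and adjusted p = 0.53 with an estimated correlation). IL6 rose by 1.95 ± 0.15 (SE) and CSF3, encoding the granulocyte growth factor, by 1.53 ± 0.15 in MDA231. In SUM159PT, 2 cytokine genes were lower and none higher (4 lower over the list alone; median -0.30, adjusted p = 0.013, and adjusted p = 0.56 with an estimated correlation). INSIG1, a feedback regulator of cholesterol synthesis, fell by 1.68 in MDA231 and rose by 0.74 in BT549, as part of cholesterol synthesis lists with 8 of 16 lower in MDA231 and 6 of 16 higher in BT549 (over the list alone 8 lower in MDA231, and 9 higher and 1 lower in BT549; adjusted p = 1.8e-04 and 2.3e-04, and adjusted p = 0.53 and 0.44 with an estimated correlation). The number higher in BT549 was 11 after repeating the quantile normalization and 13 after aligning array medians, with 0 lower under both.

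**Figure D2:**
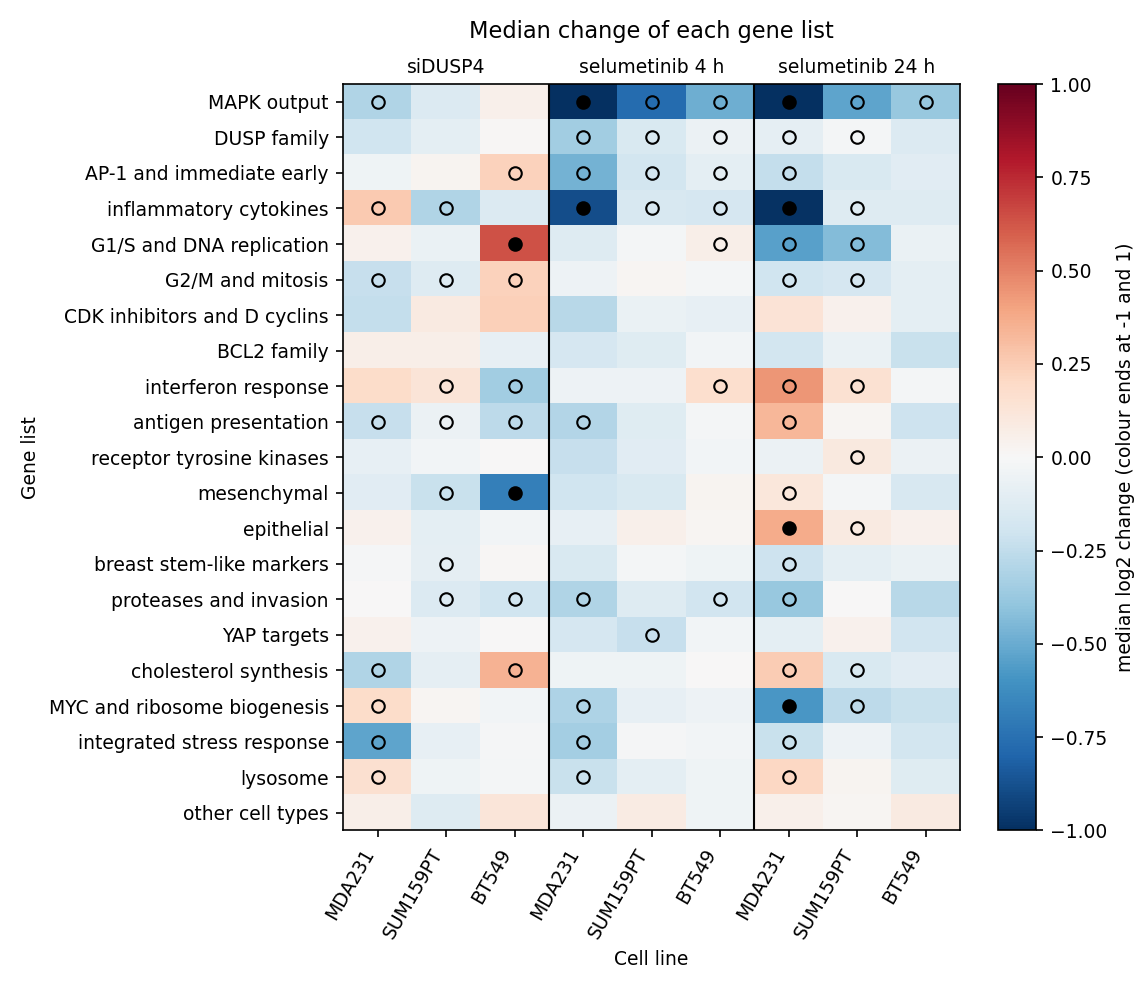
Median log2 change of each of the 21 gene lists (vertical axis) in each cell line (horizontal axis) for the 3 treatments against siCONTROL, coloured from blue (lower) to red (higher). Circles mark lists past the camera test at the preset correlation, and filled circles those that also held with an estimated correlation; in BT549 after siDUSP4 the filled circles are replication genes (median 0.64) and mesenchymal genes (median -0.68).

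After 4 h of selumetinib, ERK-dependent transcripts fell sharply in all 3 lines. Of 29 MAPK output genes, 25 were lower in the mean of the lines and none was higher, with the same numbers over the list alone. DUSP6 changed by -3.01 ± 0.12 (SE, mean log2 change), the feedback inhibitor SPRY4 by -2.83 ± 0.12, EGR1 by -2.31 ± 0.10 and HBEGF, an EGF receptor ligand gene, by -1.68 ± 0.11. In single lines, 26 of the genes were lower in MDA231, 18 in SUM159PT and 12 in BT549 (26, 21 and 17 over the list alone), with list medians of -1.16, -0.77 and -0.49. The median in the mean of the lines was -0.85, and the list had a camera adjusted p of 4.4e-45 (adjusted p = 0.0034 with an estimated correlation). For single lines the call held with an estimated correlation in MDA231 (adjusted p = 0.0044) and was lost in SUM159PT and BT549 (adjusted p = 0.055 and adjusted p = 0.058).

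**Figure D3:**
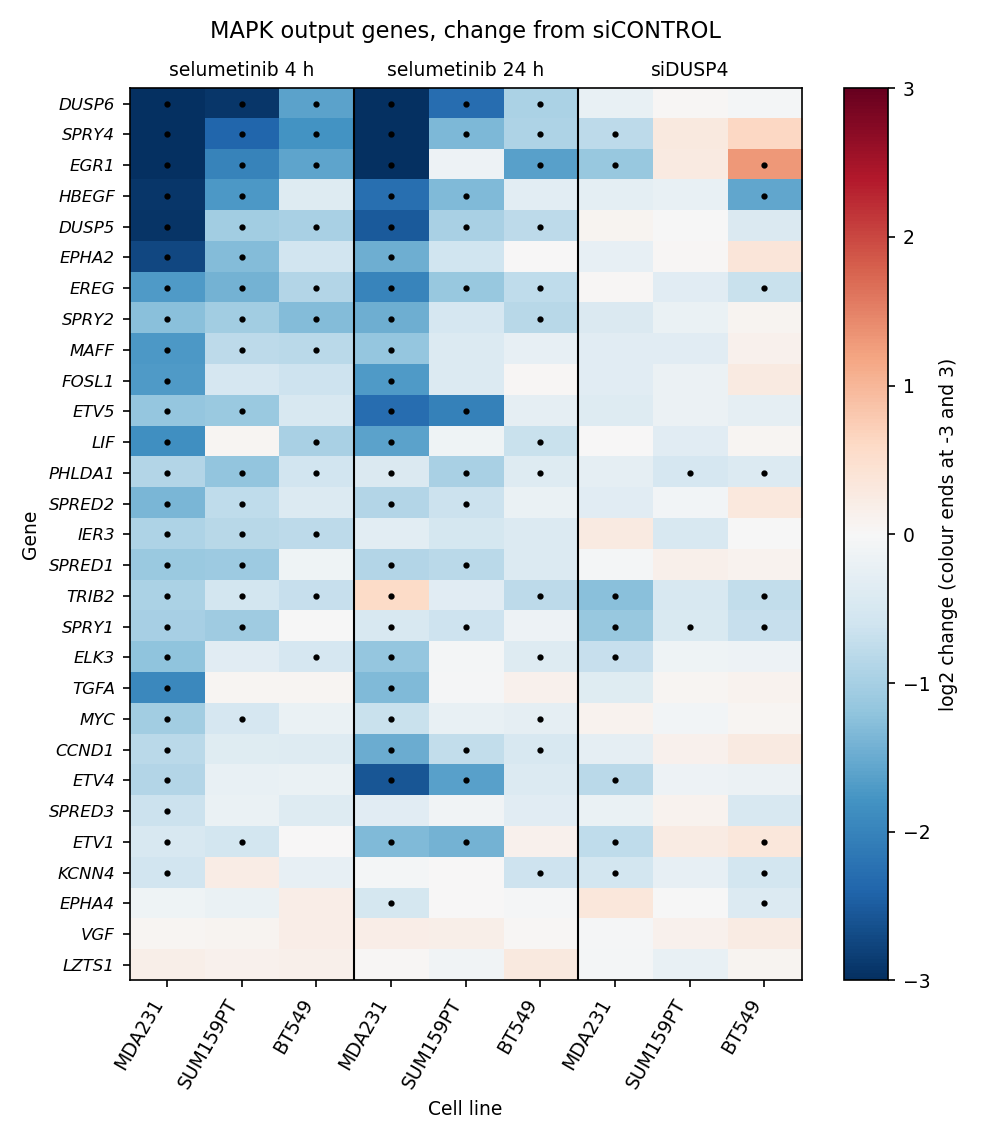
Log2 change from siCONTROL of the 29 measured MAPK output genes (vertical axis) in each cell line (horizontal axis) for 3 treatments, with colour from blue (lower) to red (higher) and a dot where the gene passed limma's test in that line. At 4 h of selumetinib 26 genes carry a dot in MDA231, 18 in SUM159PT and 12 in BT549, and with siDUSP4 8, 2 and 9 do.

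Inflammatory cytokine genes fell at 4 h, with 13 of 19 lower and none higher (14 lower over the list alone; median -0.55, adjusted p = 1.3e-13, and adjusted p = 0.0087 with an estimated correlation). CXCL8, the interleukin 8 gene, changed by -2.43, -1.50 and -1.65 in MDA231, SUM159PT and BT549. IL24 changed by -1.28 ± 0.12 and IL1B by -1.07 ± 0.11 in the mean of the lines, and IL6 fell most in SUM159PT (-1.75). AP-1 and immediate early genes had 11 of 19 lower (12 over the list alone; median -0.25, adjusted p = 2.5e-08, and adjusted p = 0.16 with an estimated correlation), including FOS and FOSL1, both AP-1 subunits, at -0.94 ± 0.09. DUSP family genes had 5 of 9 lower over all genes and over the list alone (median -0.21, adjusted p = 1.8e-04, and adjusted p = 0.2 with an estimated correlation). DUSP5 and DUSP6 are also MAPK output genes, and with only genes found on a single list the DUSP family had adjusted p = 0.41. Genes of proteases and invasion had 13 of 21 lower (15 over the list alone; median -0.22, adjusted p = 1.4e-05, and adjusted p = 0.18 with an estimated correlation), with PLAU, the urokinase gene, at -0.73 ± 0.10. In YAP targets, 5 of 14 were lower and 1 higher (7 and 1 over the list alone; adjusted p = 0.016, and adjusted p = 0.65 with an estimated correlation), and CCN2, encoding a matricellular growth factor, changed by -2.25 in MDA231 and -0.89 in SUM159PT.

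Smaller shifts were found in MYC and ribosome biogenesis, with 7 of 22 lower and 1 higher (15 and 1 over the list alone; median -0.15, adjusted p = 0.0073, and adjusted p = 0.64 with an estimated correlation), antigen presentation, with 5 of 16 lower (8 over the list alone; median -0.13, adjusted p = 0.023, and adjusted p = 0.65 with an estimated correlation), and lysosome genes, with 7 of 17 lower (8 over the list alone; median -0.15, adjusted p = 0.036, and adjusted p = 0.65 with an estimated correlation). These 3 calls and that of YAP targets ended after the quantile normalization was repeated (adjusted p = 0.3, 0.15, 0.47 and 0.098). Under that scaling, G1/S and DNA replication, G2/M and mitosis, cholesterol synthesis and interferon response genes passed the test as higher instead (adjusted p = 4.7e-05, 3.9e-06, 7.5e-04 and 0.03). As deposited, these lists had 1 higher and 1 lower of 28 genes (0 and 1 over the list alone; adjusted p = 0.27), 0 and 0 of 27 (0.17), 0 and 0 of 16 (0.21) and 2 and 2 of 25 (0.15). Their means were -0.03, -0.02, -0.02 and -0.02 and their medians -0.02, 0.00, -0.01 and 0.01, while the test pointed upward. The antigen presentation and lysosome calls also ended without the MDA231 4 h array B and the BT549 24 h array A, which had the narrowest signal range (adjusted p = 0.098 and 0.1). MYC itself fell by 0.59 ± 0.06 in the mean of the lines, and the antiapoptotic gene MCL1 by 0.62 ± 0.05.

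The remaining lists did not pass the test at 4 h. Higher and lower members numbered 0 and 3 of 9 in CDK inhibitors and D cyclins (adjusted p = 0.31; 0 and 4 over the list alone), 1 and 5 of 15 in the BCL2 family (0.096; 2 and 8), 1 and 7 of 24 in receptor tyrosine kinases (0.21; 2 and 9), 1 and 4 of 21 in mesenchymal genes (0.49), 0 and 1 of 19 in epithelial genes (0.21), 0 and 6 of 18 in breast stem-like markers (0.21; 1 and 8) and 0 and 5 of 18 in the integrated stress response (0.11). Epithelial genes had a median of -0.02 while the test pointed upward. In the blood and endothelial markers, 0 and 2 of 14 were called (adjusted p = 0.36; median -0.02, with the test upward), PECAM1 at -0.30 ± 0.08 and CD68 at -0.25 ± 0.08. Both calls ended after repeating the quantile normalization (adjusted p = 0.402 and 0.169) and on leaving out the MDA231 4 h array B (0.0513 and 0.138). The CD68 call also ended without any 1 of 12 other arrays, namely siCONTROL A and B and the 4 h array C of MDA231, all siCONTROL and 4 h arrays of SUM159PT, and siCONTROL A and the 4 h arrays A and B of BT549 (adjusted p from 0.058 to 0.117). CDKN1A, the p21 gene, fell in MDA231 (-1.48) and CCND1, the cyclin D1 gene, fell in the mean of the lines (-0.52 ± 0.07). PCDH18, a protocadherin gene, and ID3, a target of BMP signalling, had the largest mean rises as deposited (0.90 ± 0.09 and 0.73 ± 0.10).

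At 4 h, 2798 genes changed in MDA231 (200 higher, 2598 lower), 769 in SUM159PT (85 and 684), 117 in BT549 (29 and 88) and 2482 in the mean of the lines (202 and 2280). The MDA231 count rested on single arrays, being 553 without the 4 h array B, 1050 without the 4 h array C, 1501 without siCONTROL B and 6573 without the 4 h array A. The count in the mean was 1601 without the MDA231 4 h array B and 5490 without the MDA231 4 h array A. The SUM159PT count was 181 without the 4 h array A and 395, 367 and 248 without siCONTROL A, B and C. In BT549 it was 57 and 46 without siCONTROL A and B and 61, 55 and 47 without the 4 h arrays A, B and C. Lower genes made up 91.9% of the calls in the mean as deposited, 51.4% after the quantile normalization was repeated (920 higher, 974 lower) and 50.3% after aligning array medians (966 and 977). In MDA231 the shares were 92.9%, 52.3% (870 and 955) and 66.2% (528 and 1034). They were 88.9%, 62.9% (323 and 548) and 42.2% (519 and 379) in SUM159PT, and 75.2%, 59.7% (128 and 190) and 70.2% in BT549. Of the 2482 genes called in the mean, 1102 were also called after repeating the normalization. The median change of all genes in MDA231 was -0.13 as deposited, 0.01 after repeating the normalization and 0.05 after aligning medians, and in SUM159PT aligning medians moved it from -0.01 to 0.13. MAPK output genes stayed lower under both scalings, with medians of -0.71 and -0.74. Across lines, 27 genes fell and 0 rose in all 3, where independent lists would share 0.485 and 0.00153.

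**Figure D4:**
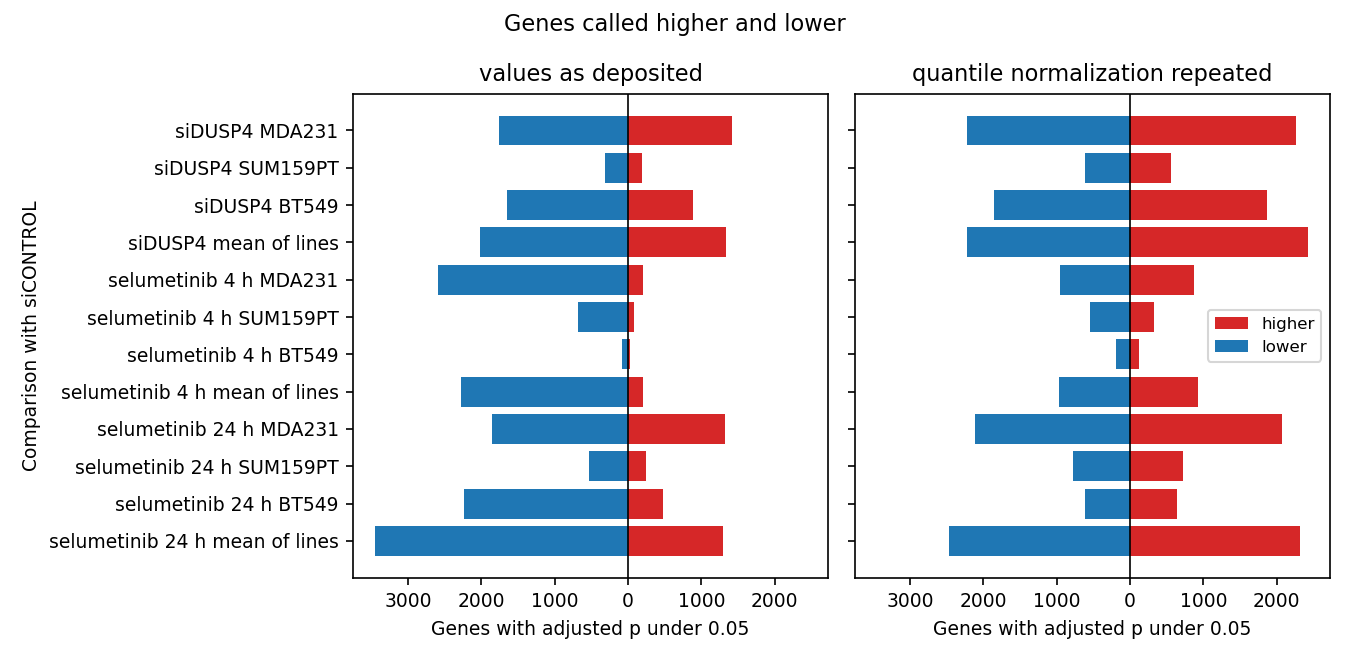
Number of genes called higher (red, to the right) and lower (blue, to the left) at limma adjusted p under 0.05, for each treatment in each line and in the mean of the lines, as deposited and after repeating the quantile normalization. As deposited, lower genes outnumbered higher ones most at 4 h of selumetinib (202 higher and 2280 lower in the mean of the lines), and after repeating the normalization the numbers were close (920 and 974).

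Some genes fell further in MDA231 than in the other lines at 4 h. DUSP6 changed by -4.53, -2.91 and -1.60 in MDA231, SUM159PT and BT549, and DUSP5, a nuclear ERK phosphatase gene, by -2.93, -1.05 and -0.97 (adjusted p of the line difference 8.45e-07 for both). TGFA, an EGF receptor ligand gene, and NLRP3, an inflammasome sensor gene, fell in MDA231 (-1.93 and -2.54), where SUM159PT and BT549 had values of 0.07 and 0.07 for TGFA and -0.05 and -0.06 for NLRP3 (none called). Of 29 MAPK output genes, 13 fell further in MDA231 than in BT549 and none the reverse (20 over the list alone; median difference -0.82, adjusted p = 1.8e-23, and adjusted p = 0.079 with an estimated correlation). Against SUM159PT, 11 fell further in MDA231 and none the reverse (16 over the list alone; median difference -0.56, adjusted p = 6.8e-10, and adjusted p = 0.94 with an estimated correlation). Over all genes, 331 differed between lines at 4 h. That count was 3834 without the MDA231 4 h array A, 185 without its array C, 203 without the MDA231 siCONTROL C, 213 and 205 without the SUM159PT siCONTROL B and C, and 214 without the SUM159PT 4 h array A.

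After 24 h of selumetinib, MAPK output genes and genes of DNA replication and ribosome biogenesis were lower in the mean of the lines. MAPK output genes had 23 of 29 lower and none higher (26 over the list alone; median -0.69, adjusted p = 9.5e-25, and adjusted p = 0.04 with an estimated correlation). DUSP6 changed by -2.13 ± 0.12 (SE, mean log2 change) and the ETS factor gene ETV5 by -1.52 ± 0.09. EGR1 fell in MDA231 (-3.54) and BT549 (-1.64), while its change in SUM159PT was -0.15 and not called. G1/S and DNA replication genes had 23 of 28 lower (24 over the list alone; median -0.37, adjusted p = 1.7e-12, and adjusted p = 0.11 with an estimated correlation), among them CDC25A at -0.76 ± 0.07 and CDC6, a replication licensing factor gene, at -0.69 ± 0.07. In single lines, 22 of the 28 were lower in MDA231 and 14 in SUM159PT (25 and 20 over the list alone; medians -0.54 and -0.43, adjusted p = 1.8e-15 and 5.4e-17, and adjusted p = 0.06 and 0.073 with an estimated correlation). In BT549 3 were lower, over all genes and over the list alone (median -0.07, adjusted p = 0.74). The BT549 median turned to 0.16 after repeating the quantile normalization, with 2 higher and 0 lower (adjusted p = 0.027), and to 0.19 after aligning array medians, with 8 higher and 0 lower (adjusted p = 0.5). The list was lower in MDA231 than in BT549 by a median difference of -0.41 (adjusted p = 2.4e-13, and adjusted p = 0.12 with an estimated correlation). MYC and ribosome biogenesis genes had 18 of 22 lower (19 over the list alone; median -0.37, adjusted p = 6.4e-12, and adjusted p = 0.04 with an estimated correlation), with ODC1 at -0.61 ± 0.05 and the nucleolar protein gene NOP58 at -0.39 ± 0.05. Of these 22, 17 were lower in MDA231, 5 in SUM159PT and 4 in BT549 (19, 12 and 9 over the list alone; adjusted p = 1.8e-15, 2.9e-09 and 0.15, and adjusted p = 0.014 and 0.073 with an estimated correlation in the first pair). In BT549 0 were lower under either other scaling, with medians of -0.04 and 0.04. G2/M and mitosis genes had 12 of 27 lower, the same number over the list alone (median -0.17, adjusted p = 4.7e-04, and adjusted p = 0.43 with an estimated correlation), or 7 lower and 1 higher after repeating the quantile normalization and 5 and 2 after aligning array medians. CCND1 fell in every line, by 1.49, 0.75 and 0.47 in MDA231, SUM159PT and BT549.

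Inflammatory cytokines remained low, with 12 of 19 lower (13 over the list alone; median -0.41, adjusted p = 2.2e-08, and adjusted p = 0.04 with an estimated correlation). CXCL8 changed by -1.90 ± 0.14 and IL24 by -1.54 ± 0.12, and IL1A, an alarmin gene, fell in MDA231 (-2.46) and SUM159PT (-0.71). AP-1 and immediate early genes had 8 of 19 lower and 1 higher over all genes and over the list alone (adjusted p = 0.0054, and adjusted p = 0.43 with an estimated correlation). DUSP family genes had 4 of 9 lower, over all genes and over the list alone (median -0.07, or 0.04 after aligning array medians; adjusted p = 0.0072, and adjusted p = 0.39 with an estimated correlation). With genes of a single list only, these AP-1 and DUSP family calls ended (adjusted p = 0.22 and 0.49). Proteases and invasion genes had 11 of 21 lower and 1 higher (14 and 2 over the list alone; median -0.23, adjusted p = 0.0034, and adjusted p = 0.39 with an estimated correlation), with the integrin gene ITGA2 at -0.54 ± 0.06, MMP1 at -0.67 ± 0.09 and the matrilysin gene MMP7 higher (0.60 ± 0.08). Integrated stress response genes had 7 of 18 lower and 1 higher (9 and 2 over the list alone; median -0.17, adjusted p = 0.0087, and adjusted p = 0.49 with an estimated correlation).

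Other groups were higher at 24 h. Epithelial genes had 8 of 19 higher and 1 lower (9 and 1 over the list alone; median 0.21, adjusted p = 7.1e-05, and adjusted p = 0.04 with an estimated correlation). KRT7, a simple epithelial keratin gene, rose by 1.55 and the tight junction gene CLDN7 by 1.09 in MDA231, CD24 rose in MDA231 and SUM159PT (0.77 and 1.23), and the tight junction gene CLDN1 fell in MDA231 (-1.22). Interferon response genes had 9 of 25 higher and 1 lower (10 and 2 over the list alone; median 0.16, adjusted p = 2.7e-04, and adjusted p = 0.39 with an estimated correlation), IFIT1 at 1.15 in MDA231 and 0.62 in SUM159PT. Antigen presentation genes had 3 of 16 higher and 1 lower, over all genes and over the list alone (median 0.09, adjusted p = 0.02, and adjusted p = 0.59 with an estimated correlation). Lysosome genes had 4 of 17 higher and 1 lower (5 and 1 over the list alone; adjusted p = 0.053), cholesterol synthesis genes 3 and 1 of 16 (0.31) and mesenchymal genes 7 and 2 of 21 (8 and 2 over the list alone; 0.062). All 3 passed as higher after repeating the quantile normalization (adjusted p = 7e-04, 0.012 and 0.019), and lysosome and mesenchymal genes also passed after aligning array medians (0.0045 and 0.031). In cholesterol synthesis the median was -0.01 and the mean 0.03, with the test upward. Its genes were 5 higher and 0 lower in MDA231 and 0 and 1 in SUM159PT (6 and 0, and 0 and 3, over the list alone; adjusted p = 0.0017 and 0.02, and adjusted p = 0.34 and 0.66 with an estimated correlation). The largest mean rises were of TNFSF10, encoding the death ligand TRAIL (1.53 ± 0.09), the fibrinogen chain gene FGG (1.38 ± 0.10, led by 3.56 in MDA231), the angiopoietin gene ANGPT1 (1.26 ± 0.09) and the mucin gene MUC1 (1.16 ± 0.12).

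Of the lists not yet described at 24 h, CDK inhibitors and D cyclins had 3 higher and 2 lower of 9 genes (adjusted p = 0.8; median -0.05, with the test upward), the BCL2 family 2 and 7 of 15 (0.2; 2 and 8 over the list alone), receptor tyrosine kinases 4 and 5 of 24 (0.53), breast stem-like markers 2 and 8 of 18 (0.17) and YAP targets 1 and 3 of 14 (0.23). The stem-like markers passed after repeating the quantile normalization (adjusted p = 0.036). BMF, a proapoptotic BH3-only gene, rose by 0.60 ± 0.08, while the antiapoptotic genes MCL1 and BCL2 fell by 0.45 ± 0.05 and 0.46 ± 0.06. PDGFRB, the PDGF receptor beta gene, rose by 0.98 in SUM159PT, and CCN2 fell by 2.49 in MDA231. Among blood and endothelial markers, 0 and 2 of 14 were called (adjusted p = 0.47), PECAM1 at -0.58 ± 0.08 and CD68 at -0.29 ± 0.08.

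In all, 3180 genes changed at 24 h in MDA231 (1322 higher, 1858 lower), 768 in SUM159PT (240 and 528), 2713 in BT549 (478 and 2235) and 4755 in the mean of the lines (1301 and 3454), with 3900 of the last having the same sign in all 3 lines. In BT549 the count was 544 without the 24 h array A, 572 without siCONTROL B and 1421 without siCONTROL C. In SUM159PT it was 462, 372 and 351 without siCONTROL A, B and C and 492, 352 and 485 without the 24 h arrays A, B and C. Lower genes made up 72.6% of the calls in the mean, 51.6% after the quantile normalization was repeated (2318 higher, 2472 lower) and 32.7% after aligning array medians (4219 and 2051). The shares in BT549 were 82.4%, 49.3% (639 and 621) and 9.56% (3890 and 411), and those in SUM159PT 68.8%, 52.1% (716 and 780) and 57.2% (460 and 614). Aligning medians moved the median change of all genes from -0.01 to 0.10 in the mean and from -0.09 to 0.17 in BT549. The medians of MAPK output, replication and ribosome biogenesis genes in the mean stayed negative under that scaling (-0.58, -0.26 and -0.26), and that of epithelial genes stayed positive (0.33). In all 3 lines, 123 genes fell and 4 rose, where independent lists would share 6.8 and 0.47. The response differed between lines for 1779 genes. NNMT, an enzyme of nicotinamide metabolism, rose by 2.49 in MDA231 with values of 0.05 and -0.05 in SUM159PT and BT549 (not called), and the cytokine gene TNFSF15 fell by 4.63 in MDA231 with values of -0.13 and -0.06 in the other lines (not called).

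Comparing the 24 h with the 4 h arrays directly, proliferation genes were lower at 24 h and part of the early response had eased. G1/S and DNA replication genes had 21 of 28 lower and none higher (22 over the list alone; median -0.35, adjusted p = 1e-25, and adjusted p = 0.033 with an estimated correlation), and MYC and ribosome biogenesis genes 11 of 22 lower (14 over the list alone; median -0.18, adjusted p = 1.6e-12, and adjusted p = 0.033 with an estimated correlation). G2/M and mitosis genes had 8 of 27 lower (12 over the list alone; adjusted p = 5.7e-10, and adjusted p = 0.22 with an estimated correlation). MAPK output genes had 12 of 29 higher and 4 lower at 24 h (15 and 4 over the list alone; median 0.20, adjusted p = 0.0074, and adjusted p = 0.69 with an estimated correlation), and AP-1 and immediate early genes 6 of 19 higher (7 higher and 1 lower over the list alone; adjusted p = 0.012, and adjusted p = 0.56 with an estimated correlation). ETV4, another ETS factor gene of the MAPK list, was among the largest falls (-1.10, from -1.67 in MDA231 and -1.41 in SUM159PT). Antigen presentation genes had 10 of 16 higher, lysosome genes 9 of 17, interferon response genes 9 of 25 and epithelial genes 7 of 19 (13, 10, 13 and 8 over the list alone; adjusted p = 1.4e-07, 3e-06, 6.1e-04 and 1.5e-04, and adjusted p = 0.24, 0.25, 0.45 and 0.073 with an estimated correlation). Receptor tyrosine kinases had 6 of 24 higher and mesenchymal genes 6 of 21 higher and 1 lower (7 and 1 over each list alone; adjusted p = 0.012 and 0.0074, and adjusted p = 0.51 and 0.24 with an estimated correlation). The other 10 lists did not pass, and in proteases and invasion the median and mean were 0.01 with the test downward.

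Between the times, 4471 genes differed in MDA231 (3666 higher at 24 h, 805 lower), 540 in SUM159PT (417 and 123), 1389 in BT549 (343 and 1046) and 2175 in the mean (1373 and 802). The MDA231 count was 2819 without the 4 h array B, and the count in the mean was 3695 without the MDA231 4 h array A. In BT549 it was 278 and 2369 without the 24 h arrays A and C and 474, 502 and 388 without the 4 h arrays A, B and C. In SUM159PT it was 297 and 328 without the 4 h arrays A and B and 359, 326 and 299 without the 24 h arrays A, B and C. The share of lower genes was 36.9% in the mean and 49.8% after repeating the quantile normalization (1740 higher, 1723 lower). In MDA231 it was 18.0%, 50.8% (2497 and 2578) or 46.1% after aligning medians (2273 and 1942), and in SUM159PT 22.8%, 45.9% (652 and 553) or 59.5% (378 and 555). In BT549 the shares were 75.3%, 52.8% (160 and 179) and 5.52% (3783 and 221). The median change of all genes was 0.12 in MDA231, or -0.01 and -0.03 under the 2 other scalings, and in BT549 aligning medians moved it from -0.07 to 0.18. TNFSF10, FGG, ANGPT1 and MUC1 were higher at 24 h than at 4 h by 1.19, 1.31, 1.35 and 1.08 in the mean of the lines.

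How far the changes after siDUSP4 resembled those after selumetinib was measured across genes. Within a line, both were compared with the same siCONTROL arrays, so chance values are shared. The correlation across genes of the siDUSP4 and 24 h changes was 0.072 in MDA231, 0.123 in SUM159PT and 0.325 in BT549. In 100 simulated pairs of unchanged groups with the same controls the means were 0.493, 0.389 and 0.381, not comparable because no gene changes there. Genes are not independent replicates, so these values carry no p. The covariance minus the simulated mean was -0.000322, 0.00106 and 0.0162, and at 4 h it was 0.0092, -0.00375 and -0.00165, where the correlations were 0.211, 0.014 and 0.132. When siDUSP4 in a line was set against the 24 h change of the other lines, which shares no arrays, the correlation was 0.019, -0.044 and -0.059. In BT549, 554 genes were lower in both siDUSP4 and 24 h selumetinib, where independent lists would share 206. The size of that overlap depended on single arrays, but it exceeded that of independent lists whichever array was left out. It was 167 without the 24 h array A, 110 without siCONTROL B and 262 without siCONTROL C, where 39.2, 28.5 and 74 would be. Higher in both were 26, where 23.7 would be, or 40 without the 24 h array A, 4 without siCONTROL B and 17 without siDUSP4 A. In BT549, 80 genes were higher with siDUSP4 and lower at 24 h, where 111 would be. The reverse held for 19, where 44.1 would be. The count of 80 was 22 and 163 without the 24 h arrays A and B, 42, 21 and 32 without siCONTROL A, B and C, and 42, 49 and 51 without siDUSP4 A, B and C. The count of 19 was 12, 8 and 11 without siCONTROL A, B and C. In MDA231, 590 genes were lower in both siDUSP4 and 4 h selumetinib, where 254 would be. Without the 4 h arrays A, B and C this overlap was 1352, 147 and 245, where 700, 50.2 and 93.9 would be, and without siCONTROL B and C it was 302 and 355, where 101 and 145 would be. At 24 h in MDA231, overlaps exceeded independent lists in all 4 combinations of direction. Both changes were higher for 206 genes, where 104 would be, and lower for 356, where 181 would be, while 250 genes were higher with siDUSP4 and lower at 24 h, where 146 would be, and 261 were lower with siDUSP4 and higher at 24 h, where 129 would be. The count of 250 was 158 and 163 without siCONTROL B and C, where 92.4 and 105 would be. The count of 261 was 163, 172 and 170 without siCONTROL A, B and C, where 82, 76.7 and 92 would be. With 3 control arrays per line the controls were not divided, and part of the excess in the same direction may come from sharing them. Single genes of the replication list went opposite ways. CDC25A rose with siDUSP4 (mean 0.83 ± 0.07) and fell at 24 h of selumetinib, and CCNE1 in MDA231 rose with siDUSP4 (2.16) and fell at 24 h (-0.60).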

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

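The counts, lists and single genes given first stood out because the effect of a treatment differed between cell lines or between times in a test of the difference itself. Other divisions of the arrays and the balance of falls and rises are given besides and were not picked in that way. Of the tests here, the one of a narrow signal range against the deeper fall of MAPK output genes in MDA231 was chosen after the result was seen.

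The change differed between lines for 2790 genes after siDUSP4, 331 after 4 h and 1779 after 24 h of selumetinib, and 2175 genes differed between 24 h and 4 h in the mean of the lines. Without the MDA231 4 h array A the last count was 3695 and the 4 h one 3834. The 4 h count was also more than 1.5 times smaller without the MDA231 4 h array C (185), MDA231 siCONTROL C (203), SUM159PT siCONTROL C (205) and B (213) or the SUM159PT 4 h array A (214). Among the genes picked by rule, 71 of 98 differed between lines after siDUSP4, 30 of 85 at 4 h and 73 of 106 at 24 h. Lists that differed between lines after siDUSP4, also with an estimated correlation, were mesenchymal genes (MDA231 minus BT549, median difference 0.62, and SUM159PT minus BT549, 0.52), G1/S and DNA replication genes (SUM159PT minus BT549, -0.69) and interferon response genes (SUM159PT minus BT549, 0.54).

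Single genes that differed after siDUSP4 included the interferon-induced genes IFIT2 (adjusted p of the line difference 3.87e-12, 1.06 in MDA231 and -1.54 in BT549) and IFIT1 (3.85e-10, 0.76 and -1.77) and the cholesterol regulator INSIG1 (3.85e-10, -1.68 and 0.74). UTS2B, encoding a urotensin peptide (5.5e-12), changed by 0.48 in MDA231 and -2.55 in BT549, and these 4 genes were called in opposite directions in the lines named. ELFN1 (5.5e-12) fell by 2.84 in BT549, while MMP3 (7.45e-12) and the trypsin inhibitor gene SPINK1 (7.58e-12) rose by 3.51 and 2.37 in MDA231. At 4 h, NLRP3 (7.39e-10), DUSP5 (8.45e-07), DUSP6 (8.45e-07), the zinc finger gene ZNF792 (8.72e-07, -1.85 in MDA231) and TGFA (8.72e-07) differed, each with its deepest value in MDA231. At 24 h the genes were NNMT (3.52e-15), RPSAP52 (7.19e-15; -3.43, -0.15 and -0.49 in MDA231, SUM159PT and BT549), the phosphodiesterase gene PDE7B (7.28e-14, 3.06 in MDA231), TNFSF15 (2.53e-13) and the endothelial cell proteoglycan gene ESM1 (3.99e-13, -2.52 in MDA231). HLA-DMB, a class II chaperone chain (9.67e-08), changed by 1.67 in MDA231 and -0.54 in BT549, and TDO2, a tryptophan-degrading enzyme (5.97e-07), by 1.55 in MDA231, -0.64 in SUM159PT and 1.08 in BT549. Among the genes picked by rule these were the 2 with opposite calls at 24 h, and at 4 h there were 0.

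Other divisions of the same arrays were refitted with limma. For 3 arrays against 3 there are 10 divisions, too few for a share under 0.05. The real one was the only 1 of the 10 to call as many genes for siDUSP4 in MDA231 (3166, highest other 0), SUM159PT (509 and 0) and BT549 (2548 and 1), for 4 h in SUM159PT (769 and 0) and BT549 (117 and 0), for 24 h in MDA231 (3180 and 41), SUM159PT (768 and 1) and BT549 (2713 and 258), and for 24 h against 4 h in MDA231 (4471 and 4031), SUM159PT (540 and 0) and BT549 (1389 and 17). At 4 h in MDA231, 3 of the 10 divisions called as many genes as the real one (2798), and the highest, 3601, put the 4 h array A together with siCONTROL B and C, which points to a structure of these arrays besides treatment. Over the 3 lines 100 divisions were drawn. Mixed groups hold treatment effects in their spread, so a share under 0.05 does not exclude chance. The real division was the only 1 of 100 to reach its count for the mean of siDUSP4 (3357, highest other 1587), 4 h (2482 and 2220) and 24 h (4755 and 959), and for the line difference after siDUSP4 (2790 and 1203). For the line difference, 4 of 100 reached 331 at 4 h (highest other 1011) and 3 reached 1779 at 24 h (3127). For 24 h against 4 h in the mean 4 reached 2175 (3341). Which arrays these highest other divisions grouped was not recorded, so the source of their higher counts is open.

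Falls outnumbered rises with selumetinib, at 91.9% of the called genes at 4 h and 72.6% at 24 h in the mean of the lines. After repeating the quantile normalization the shares were 51.4% and 51.6%, as a narrow signal range of some arrays predicted. That step makes all arrays equal by construction and would also remove a real general fall. After these values were seen, lower shares without the 2 narrowest arrays were also required, and these were 86.9% and 60.6%. With the upper quartile as a covariate the shares were 60.3% and 43.3%. At 4 h in MDA231, SUM159PT and BT549, the normalization left 52.3%, 62.9% and 59.7% and the covariate 68.8%, 46.7% and 65.6%. A narrow range was therefore not told apart from a general fall under MEK inhibition.

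MAPK output genes fell further in MDA231 than in BT549 at 4 h (median difference -0.82, 13 of 29 genes; adjusted p = 1.8e-23, and adjusted p = 0.079 with an estimated correlation). A narrow signal range as the whole cause is argued against by a median of -0.54 after repeating the quantile normalization (adjusted p = 7.4e-26) and -0.64 without the 2 narrowest arrays (adjusted p = 9.7e-25), both at the preset correlation. A higher level before treatment in MDA231 was tested across the 29 genes on siDUSP4 arrays, where 16 were higher in MDA231, and the level difference correlated with the difference in change at -0.199 (Spearman -0.116; genes are not independent). This lay at the bound of -0.2 written beforehand, and a 95% bootstrap interval of -0.547 to 0.17, required only after the value was seen, leaves that explanation open. A stronger dependence of transcription on ERK in MDA231 may also account for it and was not tested.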

How the results depend on the processing

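The alternatives were fixed before the data were examined, apart from 6 chosen after the data were seen: leaving out the 2 arrays of narrowest signal range, the upper quartile as a covariate, repeated quantile normalization for the lists and for the correlations, aligned medians for the lists, and leaving out each array in turn for the overlaps of siDUSP4 with selumetinib. The fall of DUSP4 after siDUSP4 kept its direction and call in each line under every alternative run, and without each array in turn it ran from -2.477 to -2.316 in MDA231, -1.878 to -1.77 in SUM159PT and -2.366 to -2.013 in BT549. Numbers of genes called moved far more, and the cause was not tested except where stated. No array gives a separate measure of signal over background here, so what dim signal limits was examined only by the filter on dim genes. All 19 numbers of called genes stayed within 1.5 times of the reported ones with dim genes left out, with all probes of the table and with the trend and robust options of eBayes.

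Leaving out each array in turn, the numbers called for siDUSP4 ran from 2308 to 2666 in MDA231, 290 (without siCONTROL A) to 339 in SUM159PT, 1548 (without siCONTROL B) to 2429 in BT549 and 2917 to 3287 in the mean. At 4 h they ran from 553 (without the 4 h array B) to 6573 (without the 4 h array A) in MDA231, 181 (without the 4 h array A) to 644 in SUM159PT, 46 (without siCONTROL B) to 100 in BT549 and 1601 to 5490 (without the MDA231 4 h arrays B and A) in the mean. At 24 h they ran from 2441 to 3045 in MDA231, 351 (without siCONTROL C) to 492 in SUM159PT, 544 to 3746 (without the 24 h array A, and without C) in BT549 and 3999 to 5304 in the mean. For 24 h against 4 h they ran from 2819 to 6646 (without the 4 h array B, and without A) in MDA231, 297 to 389 in SUM159PT, 278 to 2369 (without the 24 h array A, and without C) in BT549 and 1804 to 3695 in the mean. For line differences they ran from 2127 to 2864 after siDUSP4, 185 to 3834 at 4 h and 1347 to 2113 at 24 h. Fewer arrays leave less power by construction, and the cause of the rises in number was not tested.

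With the arrays of each line alone, 1838 genes were called for siDUSP4 in MDA231 and 1333 in SUM159PT, 475, 2694 and 24 at 4 h, 2052, 1937 and 1379 at 24 h, and 2526, 1610 and 529 for 24 h against 4 h in MDA231, SUM159PT and BT549. With the arrays of the 2 groups alone the numbers were 1558 for siDUSP4 in SUM159PT, 149 in MDA231 and 2074 in SUM159PT at 4 h, 1848 in SUM159PT and 15 in BT549 at 24 h, and 924 in MDA231 and 0 in BT549 for 24 h against 4 h, where limma gave 2842 genes at an unadjusted p under 0.05. At a change of at least 1.5-fold, which by construction calls fewer genes, 1201, 256 and 869 were called for siDUSP4 and 229 in the mean, 793, 288 and 70 at 4 h and 119 in the mean, 1365, 298 and 480 at 24 h and 272 in the mean, and 1618, 242 and 286 for 24 h against 4 h and 102 in the mean.

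After repeating the quantile normalization, 1175 genes were called for siDUSP4 in SUM159PT, 1825 in MDA231 and 318 in BT549 at 4 h, 1496 in SUM159PT and 1260 in BT549 at 24 h, and 1205 in SUM159PT, 339 in BT549 and 3463 in the mean for 24 h against 4 h. The line differences then numbered 4523, 746 and 2685 after siDUSP4, 4 h and 24 h. With array medians aligned the numbers were 865 in SUM159PT and 4056 in BT549 for siDUSP4, 1562 in MDA231 and 198 in BT549 at 4 h, 4301 in BT549 at 24 h, 933 in SUM159PT and 4004 in BT549 for 24 h against 4 h, and 4309 and 586 for line differences after siDUSP4 and 4 h. With array weights they were 4885, 3530, 6010 and 6082 (mean) for siDUSP4, 349, 3727 and 862 at 4 h, 6365 in MDA231, 3361 in SUM159PT and 8260 in the mean at 24 h, 1588, 1569 and 2429 for 24 h against 4 h, and 7706, 737 and 4438 for line differences.

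Without the 2 arrays of narrowest range, 1049 genes were called for siDUSP4 in SUM159PT, 908, 1882 and 297 at 4 h, 1595 in SUM159PT and 1127 in BT549 at 24 h, 1244 in SUM159PT and 607 in BT549 for 24 h against 4 h, and 4528 and 555 for line differences after siDUSP4 and 4 h. With the upper quartile as a covariate the numbers were 1237 in SUM159PT and 3987 in BT549 for siDUSP4, 676 in MDA231, 323 in BT549 and 1055 in the mean at 4 h, 1422 in SUM159PT and 890 in BT549 at 24 h, 1195 in SUM159PT, 429 in BT549 and 3727 in the mean for 24 h against 4 h, and 4906, 753 and 2773 for line differences.

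The correlation across genes of siDUSP4 with selumetinib changes, taken against selumetinib in the other lines, was 0.04 in MDA231 at 4 h and 0.019 in MDA231, -0.044 in SUM159PT and -0.059 in BT549 at 24 h, the last 2 with a turned sign. It was 0.109 in SUM159PT at 4 h and 0.258 in BT549 at 24 h with dim genes left out, and 0.119 and 0.247 after repeating the quantile normalization. Among 336 list results, the median turned sign for 81 with aligned medians, 57 after repeating the quantile normalization, 25 without the 2 narrowest arrays, 9 with dim genes left out and 5 with genes on 1 list only. Of these lists, 3, 1, 0, 0 and 2 had passed the test as reported. The direction of the test turned, with a call before or after, for 3 results. The DUSP family median was -0.02 in BT549 at 4 h (adjusted p = 0.78) and 0.05 in SUM159PT at 24 h (adjusted p = 0.96) with genes on 1 list only, which leaves fewer genes, and the G1/S and DNA replication median in BT549 at 24 h was 0.16 (adjusted p = 0.027) after repeating the quantile normalization. An estimated correlation ended 116 list calls and started 0. Lists lost and gained calls as 25 and 12 with dim genes left out, 17 and 19 after repeating the quantile normalization, 15 and 1 with genes on 1 list only, 7 and 5 without the 2 narrowest arrays, and 3 and 8 with aligned medians.

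Of 319 results for named genes, calls were lost for 28 with aligned medians, 24 with the covariate, 20 after repeating the quantile normalization, 12 with all probes of the table, 9 with array weights, 7 without the 2 narrowest arrays, 4 with trend and robust options, 4 with the line alone, 4 with the 2 groups alone and 159 at 1.5-fold. With 1 array left out, 26 of the 319 results lost their call and 2 gained it in at least 1 of the refits (169 and 5 of 5118 refits), and no picked gene changed its direction past the threshold under any alternative.

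In no line did every same-letter pair of arrays deviate together, so the letters were not taken to pair the arrays. Same-letter arrays of a line had deviations from their group means that correlated at a median of -0.0435 in MDA231, 0.0495 in SUM159PT and -0.029 in BT549 over 18 pairs each, with 22.2%, 38.9% and 5.56% of pairs over 0.1. In 1 of 18 pairs of groups, siCONTROL and 4 h in SUM159PT, all 3 same-letter pairs were over 0.1 (0.105, 0.149 and 0.271), as they were for 5 of 90 other matchings of the letters. The replicate block gave 3155, 513 and 2528 genes for siDUSP4, 2726, 790 and 97 at 4 h, and 3136, 762 and 2734 at 24 h in MDA231, SUM159PT and BT549. All 19 numbers stayed within 1.5 times, and 6 of 319 gene calls and 2 of 336 list calls were lost under the replicate block.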

Other observations

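In the tests below, that of RNA from other lines was chosen after RB1 was seen to rise but before its own result was seen. In SUM159PT, the calgranulin gene S100A8 rose by 1.86 ± 0.17 (SE) after siDUSP4 and fell by 1.28 at 24 h of selumetinib, whereas CASP14, an epidermal caspase gene, rose with both (1.63 ± 0.15 and 2.15 ± 0.15). The chemokine gene CCL20 fell in SUM159PT at 24 h (-2.52 ± 0.20) and rose in MDA231 after siDUSP4 (1.96 ± 0.20). STAT4, a cytokine-activated transcription factor gene, fell in SUM159PT with both (-1.30 and -2.04). DHRS9, a retinol dehydrogenase gene, rose after siDUSP4 in MDA231 and SUM159PT (1.47 and 1.53), with 0.13 in BT549 (not called). In BT549 the matrix protein gene MATN2 fell by 2.91 after siDUSP4. In MDA231 at 24 h, the serpin gene SERPINB3 rose by 3.40 and the fibrinogen chain gene FGB by 2.84, beside FGG. These line differences were called (adjusted p = 1.18e-06 for S100A8, 2.25e-06 for DHRS9 and 2.54e-09 for MATN2 after siDUSP4, and 5.65e-13 for SERPINB3 at 24 h).

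TFPI2, an inhibitor of tissue factor, was among the largest mean falls at 24 h (-1.66 ± 0.10; -2.32, -1.90 and -0.77 in MDA231, SUM159PT and BT549). In the separate siDUSP4 arm it rose by 1.95 in MDA231. The class II gene HLA-DPB1 fell after siDUSP4 in MDA231 and BT549 (-2.68 and -0.93), as did SLITRK6, a neuronal adhesion gene (-1.91 and -2.36). DPP4, a surface peptidase gene, and GCNT3, a mucin glycosyltransferase gene, rose in MDA231 (2.53 and 2.30). PTGS2, a prostaglandin-synthesising enzyme gene, and CCL2, a chemokine gene, rose in MDA231 after siDUSP4 (1.43 and 1.18), and in BT549 the interferon-induced gene IFI44 fell by 1.33. These last 3 genes were chosen after their values were seen.

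RB1, chosen after its values were seen, rose in BT549 after siDUSP4 by 1.20 ± 0.09 (adjusted p = 4.85e-11; group means 6.83 and 8.03), with 0.10 in SUM159PT (not called) and adjusted p = 4.74e-08 for the line difference. Because BT549 lacks intact RB1, RNA of another line in these arrays was tested. RNA of MDA231 would have to make up 12.8% of the sample, and 79 genes at least 4 log2 units higher in MDA231 would then have risen by a median of 2.21, whereas their median change was 0.08, with 6 called higher and 8 lower. RNA of SUM159PT would have to make up 26.4%, with a median rise of 3.26 for 142 such genes, and theirs was 0.08, with 7 higher and 11 lower. Both sources are argued against, and a change of the RB1 transcript itself or a second target of the siRNA may account for the rise, neither of which was tested.

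Whether shared controls alone relate siDUSP4 to 24 h changes across genes was simulated. The covariance exceeded the highest simulated one in SUM159PT (0.00547 against 0.00484) and BT549 (0.0241 against 0.0085), not in MDA231 (0.008 against 0.00891). Simulated values were tight (mean 0.00441 in SUM159PT), but real array deviations correlated at -0.425 to 0.516 in MDA231, so the test cannot decide. Against 24 h in other lines, sharing no array, correlations were 0.019 in MDA231, -0.044 in SUM159PT and -0.059 in BT549.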
